A study of Xenopus tropicalis with 9 samples.

How the data were processed

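RNA was sequenced from cells cut out by laser capture microdissection, in which a laser isolates chosen cells from a tissue section, of wild-type western clawed frogs (Xenopus tropicalis). Per the labels, the animals were untreated, were at developmental stage NF 57 and were 22 to 24 days post fertilisation at 27 to 28 °C. The 9 libraries formed 3 groups of 3: immature chondrocytes of the humerus, mature chondrocytes of the humerus, and osteoblasts of the lower jaw. Groups were taken from the cell type in the labels. How the captured areas were chosen was not given in the sources used here. The labels tie no library to a particular animal, so p-values measure the spread between these samples, which may be technical. Cell type and body site changed together in both comparisons with osteoblasts.

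Per the labels' protocols, RNA was isolated with a kit for small captured samples, treated with DNase and amplified linearly in 1 round before the library was made. The yield of amplified RNA was small, and amplification of this kind adds spread to rare transcripts. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.3a and edgeR were used by the authors. The genome build, annotation, counting method, gene filter and scaling method were not given in the sources used here. The deposited table held 10336 genes and 9 columns of whole numbers. The authors' values were treated as a score, that is, read counts scaled by 1 factor per library and rounded, because low values in several columns skipped whole numbers at regular intervals. No gene in the table had a highest value under 12.

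The spacing of the skipped and doubled values was used to estimate what 1 read was worth in each library, by the step whose rounded multiples gave the highest likelihood. It lay between 0.732 in immature replicate 2 and 1.59 in mature replicate 2. In osteoblast replicate 1 the step was close to 1 and its estimate was the least certain. Deposited totals of 7594328 to 14055110 corresponded to an estimated 7160000 to 13070000 reads. Where 1 read was worth less than 1, different read counts were rounded to the same value, so exact reads were not recovered and no count model was run.

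Values were analysed as log2(value + 9.52), where 9.52 is 1 ppm (the share times 1000000) of the mean column total, so a difference is understated for genes at low levels. Genes at 1 ppm or more of that mean total in at least 3 of the 9 libraries were tested, which left 9080 genes. The 3 groups were compared in a single limma model (limma 3.58.1 in R 4.3.3) with a variance trend. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The model uses 1 spread for all groups. On simulated data with the spread of each group, the mature against immature comparison, run on 9595 genes, recovered 0% of genes changed 2-fold, 24.2% of those changed 4-fold and 76.9% of those changed 8-fold, with 0 unchanged genes among 66 calls. The simulated comparison of mature chondrocytes with osteoblasts, run on 9591 genes, recovered 69.7% of genes changed 8-fold, and 11 of its 76 calls were unchanged genes. That of immature chondrocytes with osteoblasts, run on 9612 genes, recovered 72.3% at 8-fold, with 6 unchanged genes among 68 calls. In both simulated comparisons with osteoblasts the share of unchanged genes among the calls was above 0.05, so the adjusted p may understate the error there. Simulated genes were independent, shared 1 spread within a group, and no simulated library stood apart from its group. Libraries were also compared by Pearson correlation and principal components over the tested genes. Levels of single genes in ppm were taken relative to each library's own deposited total.

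The table named genes by Ensembl identifiers alone. The reference table used here (RefSeq genes of UCB_Xtro_10.0) paired 0 of the 10336 identifiers with a symbol, so the 27 gene lists fixed before the data were examined, among them cartilage matrix, hypertrophy and osteoblast genes, could not be tested. The rule fixed for named genes took those with the largest log2 change in each direction among called genes whose groups did not overlap, and skipped rows without a symbol. Without that exception it would name only identifiers. The 2 highest and 2 lowest of immature chondrocytes against osteoblasts were therefore followed in every comparison, a choice made after the data were examined. The tests, comparisons and most alternatives were fixed before the data were examined. The alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, the libraries in the fit, a block for the number in the sample title, a stricter threshold and each library left out. The analysis used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.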

Results

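Transcripts of 10336 genes were measured in 9 laser-captured libraries of wild-type Xenopus tropicalis at stage NF 57. Immature and mature chondrocytes, the cartilage cells before and after they enlarge and alter their matrix, came from the humerus. Osteoblasts, the cells that lay down bone, came from the angulosplenial bone of the lower jaw. Each group held 3 libraries. Deposited totals per library were 7854945 to 8860505 in the immature, 7594328 to 14055110 in the mature and 7885947 to 10886339 in the osteoblast group. The estimated read numbers behind them were 9470000 to 10730000, 7160000 to 8850000 and 7560000 to 13070000. Levels are given in ppm, the share of a library's deposited total times 1000000, and between 7069 and 8328 genes per library reached a value worth 1 ppm of the mean total.

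Cartilage and bone libraries separated clearly, and immature and mature cartilage did not. The first principal component, with 43.8% of the variance, placed all 6 cartilage libraries on one side and all 3 osteoblast libraries on the other. Correlations across genes, which are not independent replicates, were 0.95 to 0.97 among the immature libraries and 0.75 to 0.78 among the osteoblast libraries. They were 0.65 to 0.72 between cartilage and bone. Mature replicate 1 correlated at 0.95 to 0.99 with the immature libraries but at 0.82 and 0.85 with mature replicates 2 and 3, which correlated at 0.90 with each other. Its correlation of 0.99 with immature replicate 3 was the highest of the 36 pairs. The second component, with 18.6% of the variance, set mature replicates 2 and 3 apart from the other cartilage libraries. The median SD of a gene within a group was 0.34 on the log2 scale in immature chondrocytes, 0.67 in mature chondrocytes and 0.97 in osteoblasts.

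**Figure D1:**
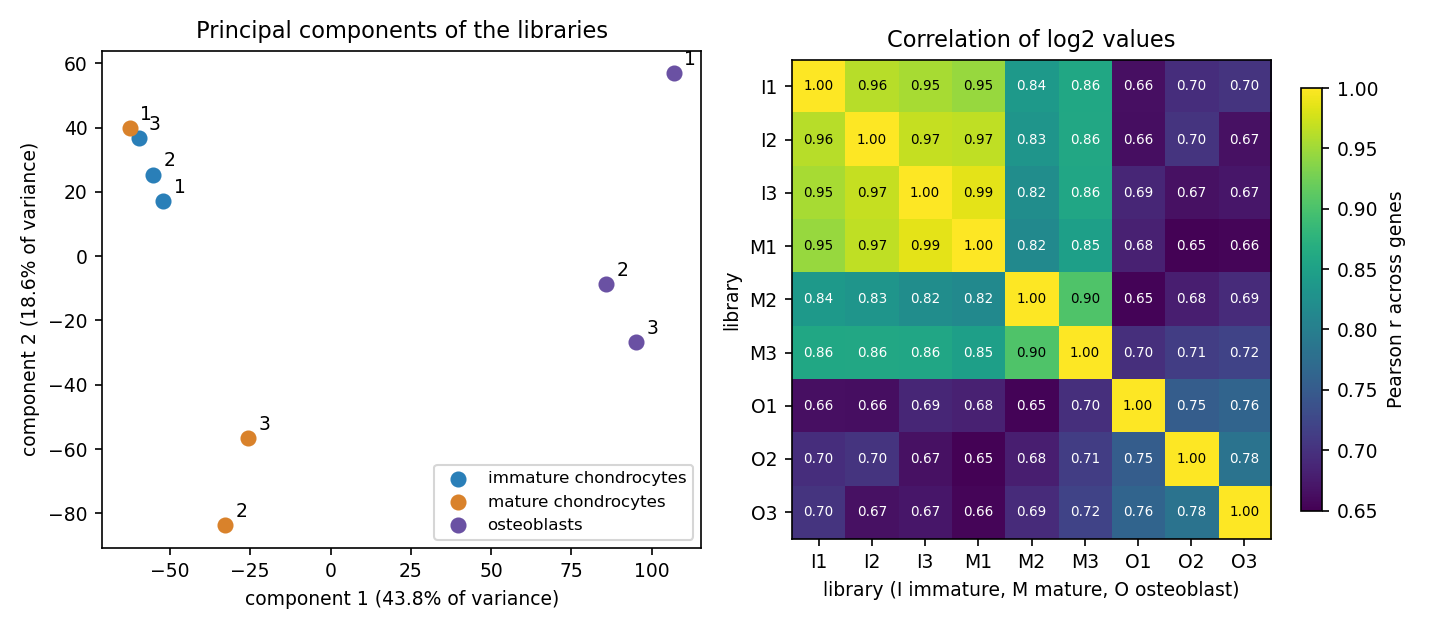
Left, the 9 libraries on the first and second principal components of log2 values, coloured by group and numbered by replicate; right, Pearson correlation across the 9080 tested genes for each pair of libraries. Mature replicate 1 lies among the immature libraries, and osteoblast libraries correlate at 0.65 to 0.72 with all cartilage libraries.

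The most abundant transcripts differed in share between cartilage and bone. The most abundant gene of osteoblasts took 9.14% ± 2.73 (SD, n = 3) of the osteoblast total, against 0.0249% ± 0.00894 (SD, n = 3) in immature and 0.136% ± 0.0998 (SD, n = 3) in mature chondrocytes. The most abundant gene of immature chondrocytes took 3.33% ± 0.531 (SD, n = 3) there, 1.72% ± 0.369 (SD, n = 3) in mature chondrocytes and 0.622% ± 0.393 (SD, n = 3) in osteoblasts. Of the 100 most abundant genes of each group, 93 were common to immature and mature chondrocytes, 81 to immature chondrocytes and osteoblasts, and 83 to mature chondrocytes and osteoblasts.

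Immature chondrocytes were compared with osteoblasts to find the genes that differ between young cartilage of the humerus and bone of the jaw. In immature chondrocytes 500 genes were higher and 707 were lower than in osteoblasts, of 9080 tested (limma, adjusted p under 0.05). The median log2 difference was 2.49 among the higher genes and -3.35 among the lower ones, and 574 genes differed at least 8-fold. In the simulated data for this comparison 6 of 68 calls were unchanged genes, a share above 0.05. ENSXETG00000001339 stood at 1191 ± 590 ppm in immature chondrocytes and 7.55 ± 8.56 in osteoblasts (SD, n = 3), a log2 difference of 7.43 (SE 1.30, limma adjusted p = 0.00175). ENSXETG00000017926 stood at 925 ± 384 and 5.82 ± 5.24 ppm (SD, n = 3), a log2 difference of 7.25 (SE 0.70, limma adjusted p = 3.69e-05). Bone was far higher for ENSXETG00000020417, at 5.91 ± 8.88 ppm in immature chondrocytes and 5239 ± 4461 in osteoblasts (SD, n = 3), a log2 difference of -10.16 (SE 0.98, limma adjusted p = 3.69e-05). It was also higher for ENSXETG00000033005, at 5126 ± 701 ppm in osteoblasts (SD, n = 3) against a highest value of 1.24 in the immature libraries, 1 of which listed it at 0. The fitted log2 difference of that gene, -11.75 (SE 1.21, limma adjusted p = 4.72e-05), depends on the pseudocount. In all, 325 genes reached 1 ppm of the mean total in every immature and no osteoblast library, and 420 did so in every osteoblast and no immature library. No other split of these 6 libraries gave more than 51 such genes. Every other split mixed cartilage and bone libraries within a group, so low counts there were largely set in advance and add no support. The 3 libraries of each group did not overlap for 34.4% of tested genes, where chance gives 10%. The number of calls fell from 1207 to between 622 and 646 when any 1 of the 3 immature libraries was left out, with 174 to 186 genes higher and 448 to 460 lower, and to 574 at an adjusted p under 0.01, with 149 higher and 425 lower.

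Mature chondrocytes were compared with osteoblasts in the same way, again with a different skeletal site in each group. In mature chondrocytes 410 genes were higher and 655 were lower than in osteoblasts (limma, adjusted p under 0.05). The median log2 difference was 2.64 among the higher genes and -3.27 among the lower ones, and 534 genes differed at least 8-fold. In the simulated data for this comparison 11 of 76 calls were unchanged genes, a share above 0.05. ENSXETG00000017926 was again higher in cartilage, at 672 ± 410 ppm in mature chondrocytes (SD, n = 3), a log2 difference of 6.96 (SE 0.70, limma adjusted p = 5.44e-05). ENSXETG00000020417 was again higher in bone, at 7.21 ± 9.69 ppm in mature chondrocytes (SD, n = 3), a log2 difference of -9.45 (SE 0.98, limma adjusted p = 6.89e-05). ENSXETG00000033005 was higher in bone too (log2 difference -7.20, SE 1.21, limma adjusted p = 0.00147), although mature replicates 2 and 3 held 121 and 90.9 ppm and replicate 1 held 1.05. ENSXETG00000001339 did not pass the test, with a log2 difference of 4.01 (SE 1.30, limma adjusted p = 0.0636). It stood at 1851 ppm in mature replicate 1, near its immature level, and at 25.8 and 9.82 in replicates 2 and 3. There were 140 genes at 1 ppm of the mean total or more in every mature and no osteoblast library and 298 in the reverse case, with at most 72 in any other split. Those splits also mixed cartilage and bone libraries, so their low counts add no support. The number of calls fell from 1065 to 688 without mature replicate 2, with 226 genes higher and 462 lower, to 756 without mature replicate 3, with 254 higher and 502 lower, and to 522 at an adjusted p under 0.01, with 142 higher and 380 lower. A fit of only the 6 libraries of both groups, which leaves out the closely matching immature libraries, gave 594 calls, 185 higher and 409 lower. With library weights 241 genes were higher and 480 lower. Without mature replicate 1 there were 945 calls, 374 higher and 571 lower, and 810 of them were among the 1065.

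**Figure D2:**
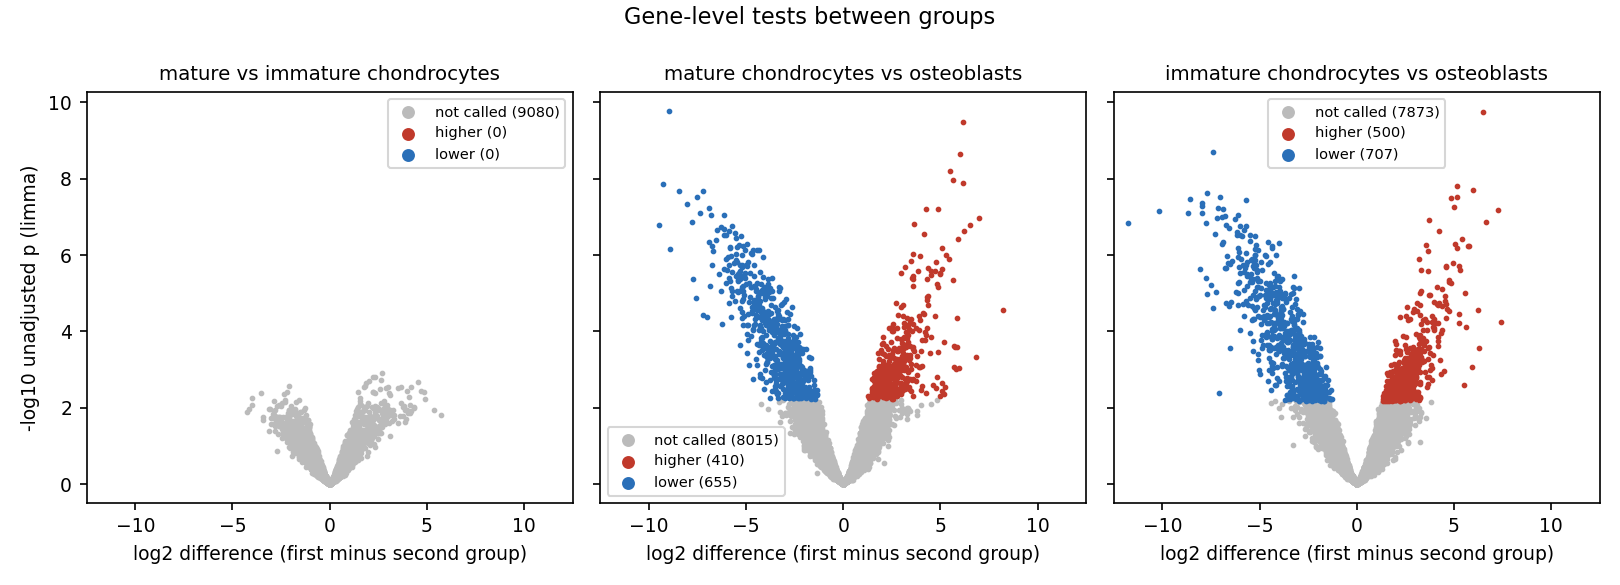
Each point is 1 of the 9080 tested genes, with its log2 difference between the 2 groups (first minus second) on the horizontal axis and -log10 of its unadjusted limma p on the vertical axis; colours mark genes with an adjusted p under 0.05. Mature against immature chondrocytes has 0 coloured points, mature chondrocytes against osteoblasts 1065 and immature chondrocytes against osteoblasts 1207.

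Mature and immature chondrocytes of the humerus were compared to follow the maturation of cartilage within 1 skeletal element. No gene passed the test: limma called 0 of 9080 genes, with a smallest adjusted p of 0.964. At an unadjusted p under 0.05 there were 457 genes, against 454 expected by chance. That match depended on the spread shared with the osteoblasts. A limma fit of only the 6 cartilage libraries gave 633 such genes and 0 calls, with a smallest adjusted p of 0.603. Fits without 1 osteoblast library gave 513 to 558 such genes and 0 calls. The groups did not overlap for 10.5% of genes, against 10% by chance. In every immature and no mature library, 41 genes reached 1 ppm of the mean total, and 7 did so in every mature and no immature library. Another split of the same 6 libraries gave 65. ENSXETG00000033005, the bone-rich gene above, had the values 1.05, 121 and 90.9 ppm in the mature libraries against at most 1.24 in the immature ones, and its adjusted p was 0.964 (limma log2 difference 4.55, SE 1.21). ENSXETG00000001339 had a log2 difference of -3.42 (SE 1.30, limma adjusted p = 0.964).

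The count of 0 rested on mature replicate 1. Without it, limma called 152 genes higher and 116 lower in mature chondrocytes, 268 in all, with median log2 differences of 3.65 and -3.23. Mature replicates 2 and 3, on which these calls rest, listed 2014 and 1430 genes at 0, against 759 to 1026 in the immature libraries. For 266 of these 268 genes, mature replicate 1 lay nearer to the immature mean than to that of the other mature libraries. Leaving out any other library gave 0 calls, and weighting libraries by their agreement with their group gave 468, of which 240 were higher. The weights were 0.503 for mature replicate 1 and lower still for the osteoblasts, at 0.298, 0.467 and 0.420. They were 0.760 and 1.37 for mature replicates 2 and 3, and 2.34, 5.44 and 2.56 for the immature libraries. The 468 calls can therefore also come from a smaller part of the osteoblast spread in the model or from the high immature weights. Without weights, the fit of only the 6 cartilage libraries, which holds no osteoblast spread but fewer libraries, gave 0 calls. The unadjusted 95% interval of a log2 difference was ± 1.43 for the median gene. On simulated data the adjusted test recovered 0% of genes changed 2-fold, 24.2% of those changed 4-fold and 76.9% of those changed 8-fold. The simulation kept genes independent and held no library that stood apart from its group, so these rates may not hold for the mature group here.

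**Figure D3:**
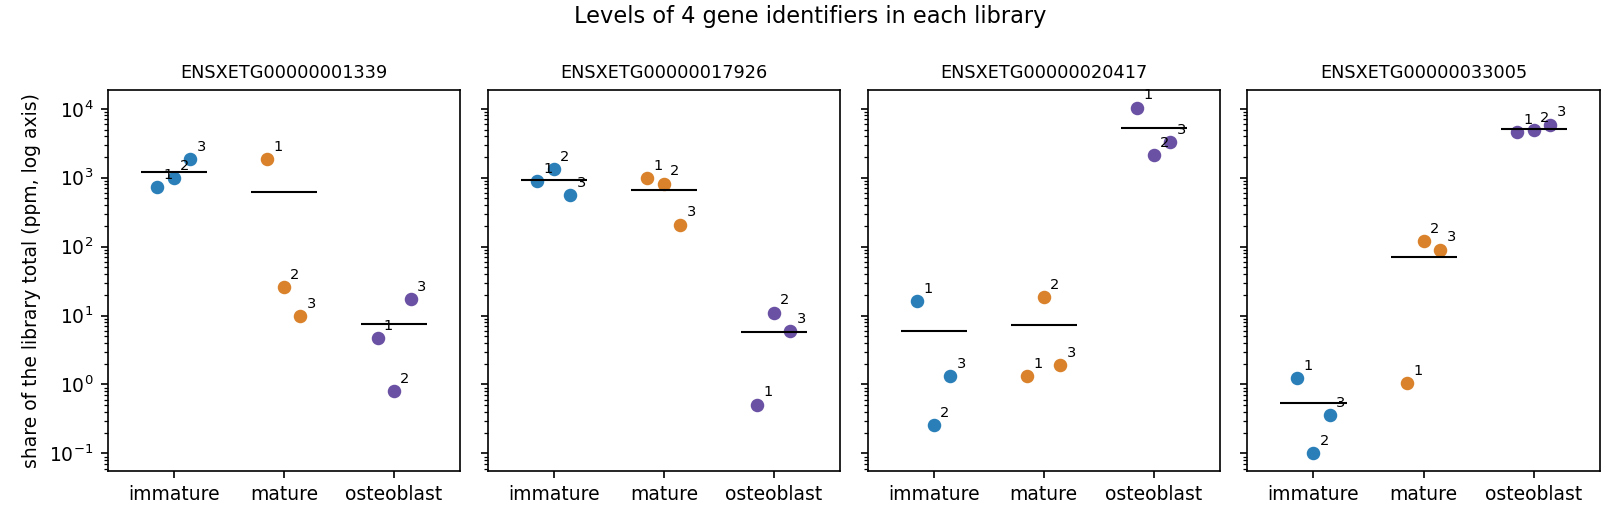
Share of the library total in ppm (log axis) of 4 gene identifiers in each of the 9 libraries, numbered by replicate; the line is the group mean and a value of 0 is drawn at the bottom of the axis. In ENSXETG00000001339 and ENSXETG00000033005, mature replicate 1 (1851 and 1.05 ppm) lies with the immature libraries and away from mature replicates 2 and 3.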

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

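The alternatives were fixed before the data were examined, apart from bringing every library to the same total, which was chosen after seeing the data. The 0 genes called between mature and immature chondrocytes held in 12 of 13 settings, and library weights gave 468. The stricter threshold, 1 of those 12, could give only 0. Leave-one-out counts ran from 0 to 268, the latter without mature replicate 1. Mature chondrocytes against osteoblasts gave 1065 genes, 594 with only the 6 libraries of both groups and 522 at an adjusted p under 0.01. Leave-one-out counts ran from 688 to 1273. Immature chondrocytes against osteoblasts gave 1207 genes and 574 at an adjusted p under 0.01, with leave-one-out counts from 622 to 1396. All other total counts in these settings stayed within 1.5 times the main one. In the comparisons with osteoblasts, no gene called in both fits changed direction in any of the 13 settings. A gene that passes in 2 fits of the same libraries can hardly reverse, so this adds little. Bringing libraries to the same total moved the median log2 difference of all genes between mature and immature chondrocytes from -0.09 to -0.37, and from 0.12 to -0.05 for mature chondrocytes against osteoblasts. Of the 4 identifiers in both comparisons with osteoblasts, 1 changed its call: ENSXETG00000001339 passed for mature chondrocytes without mature replicate 3 (log2 difference 5.28, limma adjusted p = 0.0333; range over its alternatives 0.0333 to 0.228). Each pair of groups shares only 1 title number, and deviations of the libraries that share one correlated at 0.32 (the highest of 27 pairs across groups), -0.10 and 0.10 across genes. A pairing was not shown and stays possible. With them as a random block, 0, 1204 and 1396 genes were called. Count models were not run because exact reads were not recovered, and no gene list alternative was run without gene names.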

Other observations

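All tests below other than the splits of the libraries were chosen after the results were seen. Genes that set bone apart from cartilage as a whole were taken by comparing osteoblasts with the mean of both chondrocyte groups (limma, adjusted p under 0.05), which gave 831 genes higher in bone and 653 higher in cartilage. These sets come from the same libraries, and the larger spread of the mature group can bias their selection. On average the bone genes lay at 4.92 ± 0.03 (SD, n = 3) on the log2 scale in immature chondrocytes, 5.08 ± 0.21 in mature chondrocytes and 8.26 ± 0.20 in osteoblasts. The step from immature to mature was 4.89% of the way to osteoblasts. It rested on mature replicates 2 and 3, at 5.10 and 5.28, while mature replicate 1, at 4.87, lay below every immature library. For the same genes the step was 0.27, or 8.12% of the way, without mature replicate 1 and 0.07, or 1.99%, without mature replicate 3. Of the 831 genes, the mean was higher in mature chondrocytes for 409, lower for 355 and equal for 67, of which 63 were listed at 0 in all 6 cartilage libraries. The mean log2 difference was 0.16 against -0.12 for all other genes, and the median was 0.00, or 0.08 without the 67 equal genes. With a preset correlation between genes, camera gave the bone set an adjusted p of 0.00265, but with an estimated correlation it was 0.241, and fry, which makes no comparison with other genes, gave 0.747. With the same genes kept throughout, it was under 0.05 in 14 of 16 alternatives and ranged from 3.99e-05 to 0.747. Those 14 all used camera with the preset correlation, which is lower than the estimated 0.034, so they do not test that setting. With the set selected anew under each alternative, the camera adjusted p of the bone set was 0.0784 without osteoblast replicate 3. An exact two-sided permutation test of the 3 against 3 library means gave p = 0.4, where 0.1 is the smallest possible. The cartilage genes had a mean log2 difference of -0.04 and a median of -0.05, while camera placed them upward relative to other genes with an adjusted p of 0.561. With the same 653 genes kept, the set was called among these alternatives only without mature replicate 3 (upward, adjusted p = 0.0325), with a range of 0.0325 to 0.967. Without mature replicate 1 these genes had a mean log2 difference of -0.15 and an adjusted p of 0.644. Selected anew under each alternative, the cartilage set was called upward without mature replicate 1 (adjusted p = 0.00292) and without mature replicate 3 (0.0253), so its direction without mature replicate 1 depends on the selection. With a mature library left out, the mature mean varies more than the immature one. Selecting anew then favours genes with high mature values, which biases the cartilage set upward, so these 2 results are no support for a rise. Both calls used camera with the preset correlation. With an estimated correlation, camera gave the 653 genes an adjusted p of 0.790 over all libraries.

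The slightly higher level of bone genes in mature cartilage was weighed against a floor effect and carried-over osteoblast RNA, and neither was excluded. Random lists of other genes at the same cartilage level lay 0.199 lower on the log2 scale, but with their spread widened for the estimated correlation between genes the normal p was 0.0990 two-sided and 0.0495 one-sided. Osteoblast RNA like that of the jaw libraries would have to make up 1.84% of mature replicates 2 and 3 to give the level of the most abundant bone gene. Of 13 other genes at 100 ppm or more in every osteoblast library and under 0.5 times the level needed in immature cartilage, 7 stayed under that bound in both libraries (4.36 expected from other genes at such levels, exact one-sided Poisson-binomial test, p = 0.106), including 3 listed at 0 in both (0.533 expected, p = 0.0130 by the same exact test), which lie near the floor. That share, a smaller one, with 53.8% of the 13 genes above every immature library in both, a real rise in maturing cartilage and chance all stay open.

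Mature replicate 1 lay with the immature libraries. On the line from the immature libraries (0) to mature replicates 2 and 3 (1), immature libraries placed without their own values reached at most 0.121, so no immature library took the place a swap between the groups would need. Mature replicates 2 and 3, each placed on the line to the other alone, reached 0.728 and 0.571, short of 1. The closest partner of mature replicate 1, immature replicate 3, differed from it by 7.35 times counting noise on estimated reads, too much for a single library deposited under 2 names. Over the 2270 most abundant genes its correlation with the immature libraries still exceeded that with mature replicates 2 and 3 by 0.153, which argues against a loss of rare transcripts in those libraries as the cause, although they list 2014 and 1430 genes at 0. Its own position was -0.0262, which is consistent with immature cartilage in the captured area or a wrong label, and an animal whose mature zone differed less from its immature zone, untested, would give the same value.

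The 152 genes that were higher in mature cartilage without replicate 1 averaged 9.90 and 10.05 on the log2 scale in mature replicates 2 and 3 and 5.98 to 6.16 in the immature libraries. They averaged 7.08 to 7.51 in osteoblasts. Carried-over RNA like that of the jaw osteoblast libraries could not raise a gene above its level there, yet 70.4% of the 152 genes (107) exceeded every osteoblast library in both, which argues against such RNA as the source of most of them. Bone of the humerus, which no library measures, a rise during maturation, other cell types near the mature zone, and a difference between these 2 libraries and the rest stay open, as no marker genes could be identified. Immature replicate 3, which shares a title number with mature replicate 3, averaged 5.98 for the 152 genes. It was among the libraries that selected these genes as low, so its level cannot tell what the shared number means. The 116 lower genes averaged 4.72 and 5.16 in mature replicates 2 and 3, 8.22 to 8.51 in the immature libraries and 5.99 to 6.20 in osteoblasts. Whether loss of transcripts in those 2 mature libraries contributed to them was not tested.

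Splitting the 6 libraries of a comparison into 3 and 3 is possible in 10 ways, too few for a share under 0.05. For mature against immature chondrocytes all 10 splits gave 0 called genes. For mature chondrocytes against osteoblasts the real split, the only 1 with as many, gave 1065 and the highest other 0. For immature chondrocytes against osteoblasts the real split, again the only 1, gave 1207 and the highest other 0. In both comparisons with osteoblasts every other split mixed cartilage and bone libraries within a group, which widens the spread. The 0 calls there were largely set in advance and add no support to the real counts.

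Osteoblast libraries each held genes that were high in that library alone. A gene counted if its value was worth 10 ppm of the mean total or more. It also had to reach at least 8 times the sum of the next highest value and 1 ppm of the mean total. There were 68 such genes in osteoblast replicate 1, 30 in replicate 2 and 54 in replicate 3. The mature libraries held 0, 3 and 1, and the immature libraries 0. Cartilage libraries have more close counterparts among the libraries than osteoblast libraries do, which by itself can lower their counts.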
